A study of Homo sapiens with 2 samples.

How the data were processed

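Gene expression was measured in 22RV1 cells, an established human castration-resistant prostate carcinoma cell line, on 2 single-colour (Cy3) oligonucleotide arrays of the Agilent SurePrint G3 Human GE v3 type. Per the labels' protocols, cells were plated 48 h before transfection, received a synthetic miR-1908 mimic or a negative control mimic at 10 nM for 24 h, and were lysed for RNA 48 h after a medium change. From each culture 100 ng of RNA was labelled after amplification. Each group held 1 array, and the labels did not say whether the mimic carried the 5p or the 3p strand of miR-1908.

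The deposited intensity values were made with Agilent Feature Extraction 11.5.1.1, per the file headers and the submitters' processing notes. The processed signal of a spot is a linear brightness from which background was subtracted and which was detrended across the array, per the file headers, with substitute values for spots near background. The authors' deposited log2 value table was also read. Set against the scanner files, each of its columns was log2 of the processed signal less 1 constant (5.95 for the control array and 5.80 for the mimic array, within 0.001 for 100% of gene probes). The table was therefore not centred per gene and ran in the same direction, with column medians of -3.39 and -3.29. The constants lay close to the 75th percentiles used here (5.96 and 5.81), so that table is nearly the main setting and not an independent check. Probe positions are those of the files, on the human genome build hg19. Whether a probe lay in an exon or a UTR was not looked up, since no annotation of that build was used.

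The main value was log2 of the processed signal less the array's 75th percentile, after control spots and spots marked as outliers were left out. Spots of one probe were averaged, which left 58200 probes of 60 bases, and 1 gene probe without an accepted spot on both arrays was left out. Names followed the accession in the files where a gene-name table of assembly GRCh38.p14 held it (31104 probes), then a current symbol or unique synonym (3862 probes), then another probe of the same file name (180 probes). The other 23054 probes kept the name in the files. A gene was represented by its brightest probe, among those well above background on both arrays where there were any, which gave 43271 genes or names. No gene spot was saturated. Differences are the miR-1908 mimic array minus the control array on the log2 scale.

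With 1 array per group there was no estimate of the spread between cultures, no test was made and no p-value is given. A difference of at least 2-fold was used as a size threshold. Technical spread was read from probes printed in 10 spots and from E1A spike-in RNA probes, and it covers labelled material on these 2 arrays, not separate cultures. Both arrays lay on the same slide and were scanned in the same run, so neither slide nor scan differed between the groups. Counts of genes and list members use measured values. A gene well above background on only 1 array also has a lower bound for its difference: the bright value against the higher of the dim probe's own value and the lowest value among probes well above background on the dim array.

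In total 30 gene lists were fixed before the data were examined. They covered polyamine metabolism, published miR-1908 targets, vesicle formation, trafficking and cargo, lysosomes, androgen-regulated genes, proliferation, stress, inflammation, metabolism, small RNA machinery, housekeeping genes and markers of other cell types. The median of each list was placed among the medians of 10000 random lists of the same size, matched on mean level in 20 bins. A list was called apart when its percentile was under 2.5 or above 97.5, which chance alone would nominally give for 1.5 of 30 lists. Named genes were SRM and the published targets, and the 12 highest and 12 lowest differences among genes in the brighter part of those well above background on both arrays. They also included the 4 largest bounds each way and up to 4 members per list with the largest absolute difference. Any other gene that is named was chosen after its value was seen, as stated beside it. Some genes that this rule selected, and the median of the list of published targets, are not reported here.

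The steps were tested on simulated data with the 22820 genes of this comparison. At a log2 fold of 2, 100% of the altered genes passed the 2-fold threshold and 0 unaltered genes did. The simulated noise was equal for all genes and small against that threshold, so this outcome was near certain beforehand. Of 200 random lists of real differences, 8% were called apart, and 100% of 200 lists shifted by 0.5 were. That shift is larger than the median of any list called apart here (-0.34 to 0.34), and smaller shifts were not tried. Alternatives were normexp background correction with an offset of 50, median scaling, quantile normalization, the authors' table, the mean of a gene's probes, bright probes alone, no background filter and a floor of 20. Thresholds of 1.5-fold and 3-fold, matching in 50 bins and list means were also run. Scaling on the spike-ins, removal of a trend with probe GC content and a search of probe sequences for seed matches were chosen after seeing the data. A planned search of 3' UTRs for seed matches was not run, since no transcript sequences were used here. Computation used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.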

Results

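The series addresses spermidine synthase, encoded by SRM, and the release of extracellular vesicles by castration-resistant prostate cancer cells. Transcript levels were compared between 22RV1 cells given a miR-1908 mimic (1 array) and cells given a negative control mimic (1 array). On the control array 27287 of 58200 gene probes (46.9%) were well above background, and on the mimic array 27858 (47.9%). The 75th percentile of the processed signal was 62.2 on the control array and 55.9 on the mimic array. Across the 285 probes with 10 spots that were well above background on both arrays, the log2 difference of a single spot had a technical SD of 0.14. It was 0.10 in their brighter part and 0.17 in their dimmer part. No value below has a replicate check, so each difference describes these 2 arrays and was not compared with the spread between cultures, which the number of arrays left unmeasured.

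The first question was whether SRM itself, the gene that joins decarboxylated S-adenosylmethionine to putrescine to make spermidine, differed with the mimic. SRM was 2.34-fold lower in the miR-1908 mimic array, with a processed signal of 411 against 1068 in the control and a log2 difference of -1.23. It rested on 1 probe (NM_003132, chromosome 1, 11115982 to 11116125 in hg19; the interval is longer than the 60-base probe). Among the 10023 genes of the brighter set, SRM had the 25th lowest difference. Published miR-1908 targets that were compared lay within 2-fold. APOE, a lipoprotein component, was higher by 0.45 on the log2 scale (474 in the control and 582 with the mimic), and DNAJA4, a co-chaperone, was at -0.37.

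Most other genes of polyamine metabolism lay within 2-fold. Of 26 measured members, 1 was at least 2-fold higher, 1 was at least 2-fold lower (SRM) and 24 lay within 2-fold. The higher one was SMOX, the spermine oxidase, at 1.16, with low signals of 27.2 and 54.6. AZIN2, an antizyme inhibitor, was at 0.93 and EIF5A2, which carries the spermidine-derived residue hypusine, was at 0.84, both also dim. ODC1 and AMD1, the enzymes upstream of SRM in the pathway, were at 0.39 and -0.09, and SMS, which uses spermidine, was at -0.27; these 3 were chosen after their values were seen. The list median was -0.12 (percentile 16.8), so the list as a whole was not apart from matched lists. SMOX was at 0.49 after normexp correction, which draws dim probes together.

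Vesicle genes were examined next, because the series concerns vesicle secretion. None of the 35 measured genes for forming intraluminal vesicles, through the ESCRT machinery or otherwise, differed by 2-fold. Their median was -0.08 (percentile 31.3), and the members furthest from 0 were SMPD2, a neutral sphingomyelinase, at -0.57, STAM2 at 0.55, MVB12A at -0.54 and VPS37C at -0.47. Among 53 measured genes of vesicle trafficking and release, 2 were at least 2-fold higher and 51 lay within 2-fold. These 2 were PLD1, a phospholipase D, at 1.94, and RAB31, an endosomal small GTPase, at 1.83 (109 in the control and 351 with the mimic). SYT7, a calcium sensor for exocytosis, was at -0.94, and RAB27B, a GTPase of vesicle docking, was at -0.80, with -0.45 from its second probe. The median of that list was 0.04 (percentile 90.8). It was called apart, at percentile 98.8, only after quantile normalization. PLD1 was dim (8.82 and 30.4) and was at 0.50 after normexp correction.

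Vesicle cargo markers and lysosomal genes were also close to the matched lists. Of 31 measured cargo markers, 1 was at least 2-fold higher, MFGE8, a secreted phosphatidylserine-binding protein, at 1.13 with signals of 10.8 and 21.2. The tetraspanin TSPAN6 was at 0.98, and CAV1, the caveolar coat protein, and ANXA1, an annexin, were both at -0.97. The list median was -0.05 (percentile 58.6). All 35 measured lysosome and autophagy genes lay within 2-fold, with a median of 0.02 (percentile 91.2). Their largest differences were MCOLN1, a lysosomal cation channel, at -0.89, GABARAPL1 at 0.75, CTSZ at 0.65 and the autophagy receptor SQSTM1 at 0.58. A second, dimmer CTSZ probe was at -0.26, in the opposite direction.

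Across all genes, the 2 arrays were close to each other, and more genes were at least 2-fold higher than lower with the mimic under the main scaling, a split that turned under spike-in scaling. Of 20046 genes well above background on both arrays, 85.8% differed by less than 1.5-fold, 498 were at least 2-fold higher and 259 were at least 2-fold lower. Counting genes well above background on at least 1 array (22820), 1400 were higher and 1014 lower by measured values. Some of these values lay near background on 1 array, where only a lower bound is known. The 12 highest named genes of the brighter set were led by AKAP12, a scaffold for protein kinase A, at 3.23 (78.5 and 662), and STMN4, a stathmin family member, at 3.01. SLC45A3, a prostate-enriched transporter, was at 2.81 (766 and 4833), and SPOCK2, a matrix proteoglycan, at 2.75. TMPRSS2, a serine protease of prostate epithelium, was at 2.41 and CEND1 at 2.25, and the other 6 were metallothionein genes. The AKAP12 difference was 3.15 on a second probe, whereas a second SPOCK2 probe was at 0.15.

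The 12 lowest named genes of the brighter set lay between -1.64 and -1.31. They were ADISSP (6145 and 1769), FKBP8, AKT1S1, SSTR1, SOD3, AKR1C1, FAAP20, ZDHHC12, ATF5, AATF, AQP3 and EEF1A2. AKT1S1 encodes an mTORC1 inhibitor and was at -1.61; SSTR1 encodes a somatostatin receptor and was at -1.54. SOD3, the extracellular superoxide dismutase, was at -1.52, ATF5, a stress-responsive transcription factor, at -1.43, and AQP3, a water and glycerol channel, at -1.32. Second probes gave -1.57 for ADISSP, -1.50 for ZDHHC12 and -1.28 for AQP3. FAAP20 is uncertain, because its chosen probe was at -1.49 and the other 4 probes well above background on both arrays lay between -0.06 and 0.74.

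Some genes were well above background on 1 array alone. PPIL6, a cyclophilin-like gene, was at least 42.8-fold lower with the mimic (273 in the control), IGFBP5, an insulin-like growth factor binding protein, at least 17.8-fold, the pseudogene UOX at least 17.5-fold and CPS1-IT1 at least 14.9-fold. In the other direction TFAP2B, a transcription factor, was at least 17.9-fold higher (106 with the mimic), SPATC1 at least 9.96-fold, PLB1 at least 9.80-fold and ADGRG2 at least 8.84-fold. Each rested on 1 spot per array. Further probes of PPIL6, SPATC1, PLB1 and ADGRG2 were not well above background on either array. In all, 1585 genes were well above background with the mimic alone, 424 of them with a bound of at least 2-fold. For the control alone the numbers were 1156 and 434.

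These counts depended on how dim signals and the scale between arrays were treated. After normexp correction 99 genes were at least 2-fold higher and 96 lower, among genes well above background on at least 1 array. Spike-in probes for E1A RNA had a median raw difference of 0.02 between arrays, while the 75th percentiles differed by -0.15. Scaling on those probes, an alternative chosen after seeing the data, placed the median of genes well above background on both arrays at -0.19 in place of -0.02. It gave 323 higher and 480 lower genes in place of 498 and 259, so that the higher share went from 65.8% to 40.2%. All differences here are relative to the 75th percentile, and list percentiles are not altered by such a shift.

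**Figure D1:**
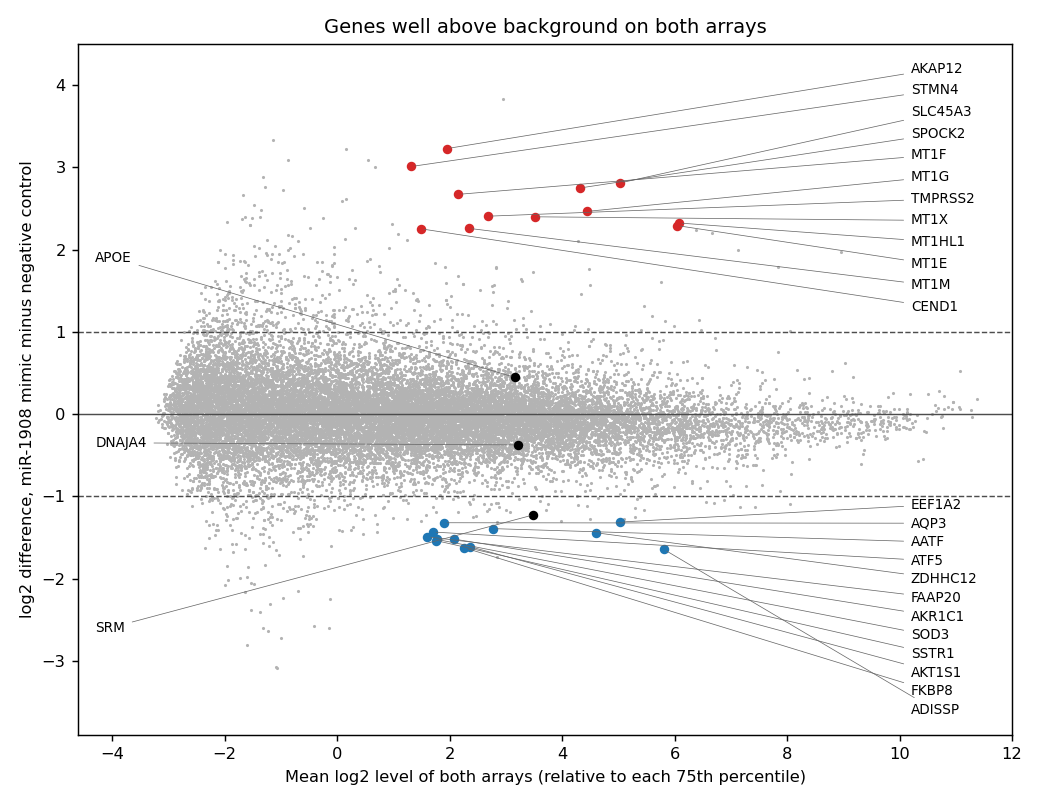
Log2 difference (miR-1908 mimic minus negative control mimic, y axis) against the mean log2 level of both arrays relative to each 75th percentile (x axis), 1 grey point per gene well above background on both arrays (20046 genes). Red points are the 12 highest and blue points the 12 lowest named genes, black points are SRM (-1.23), APOE and DNAJA4, and dashed lines mark 2-fold.

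Androgen-regulated genes were higher with the mimic as a list. Of 32 measured targets, 4 were at least 2-fold higher, 0 were at least 2-fold lower, and 22 lay above 0. The 4 were SLC45A3 at 2.81, TMPRSS2 at 2.41 (173 and 827), STEAP1 at 1.07 (2727 and 5167) and STEAP4. A second STEAP1 probe gave 1.24. STEAP4 was well above background with the mimic alone and at least 1.54-fold higher, so its 2-fold call rests on a dim control value. Among members well above background on both arrays, 3 were at least 2-fold higher. The list median of 0.34 lay above all 10000 matched lists. Neuroendocrine markers, which mark an androgen-independent cell state, had a median of -0.21 over 15 measured genes (percentile 4.83). None differed by 2-fold. FOXA2 was at 0.89 and POU3F2 at 0.82, while the prohormone convertase PCSK1 (at least 1.56-fold) and the granin SCG2 (at least 1.75-fold) were lower and were above background in the control alone.

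Genes of cell proliferation and growth were lower with the mimic as lists, by less than 2-fold for each member except SRM. For S phase and DNA replication, 43 of 44 measured genes lay below 0, with a median of -0.34, below all 10000 matched lists. The transcription factor E2F1 was at -0.79, the replicative helicase subunit MCM5 at -0.75 (1026 and 548), the ribonucleotide reductase subunit RRM2 at -0.61 and thymidylate synthase, TYMS, at -0.60 (5015 and 2980). Dimmer RRM2 probes were at 0.22 and -0.12, so its probes disagree. Ribosome biogenesis genes and MYC targets had 39 of 44 members below 0 and a median of -0.33, also below all matched lists. After SRM (-1.23), the furthest were UTP20 at -0.83, NOP16 at -0.76 and MYC itself at -0.68 (3068 and 1723). Mitosis genes had 37 of 45 members below 0 and a median of -0.17 (percentile 1.72), with AURKB at -0.46, SPC25 at -0.42, MKI67 at -0.41 and AURKA at -0.32. The call for mitosis was lost after normexp correction, quantile normalization or GC correction, and with the mean in place of the median.

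Other abundant growth-related classes were close to their matched lists. The 40 ribosomal protein genes had a median of -0.13 (percentile 45.3), with RPS28 at -0.57 and RPL7, RPS23 and RPL27 between -0.31 and -0.29. The 24 measured replication-dependent histone genes had a median of -0.11 (percentile 24.6), with H2BC12 at 0.80, H2AX at -0.58, H3C1 at 0.48 and H1-5 at -0.37. Histone copies are near-identical, so values of single histone genes are uncertain. The 17 housekeeping reference genes had a median of -0.10 (percentile 44.8), with B2M at 0.84, TFRC and ACTB both at -0.61 and HPRT1 at -0.30. A second ACTB probe was at 0.13 (2233 and 2197), so the direction of ACTB is uncertain.

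Immediate early and growth factor response genes were higher with the mimic as a list. Of 28 measured members, 4 were at least 2-fold higher, 24 lay within 2-fold and 23 lay above 0. The 4 were PHLDA1 at 1.61, FOS, an AP-1 subunit, at 1.41 (59.7 and 143), KLF2 at 1.40 (103 and 244) and SPRY4, a feedback inhibitor of receptor tyrosine kinase signalling, at 1.28. The lowest were MYC at -0.68 and ETV4 at -0.55. The list median of 0.26 lay above all 10000 matched lists. A second SPRY4 probe, well above background on both arrays but dim, was at -0.01, and after normexp correction none of the 4 reached 2-fold (0.46, 0.89, 0.97 and 0.64 in the order named).

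Interferon and inflammatory genes were higher as lists, at low signals. Of 26 measured type I interferon response genes, 5 were at least 2-fold higher, 0 were at least 2-fold lower and 21 lay above 0, with a median of 0.25 (percentile 99.8). IFIT1 (at least 1.92-fold) and IFIT2 (at least 2.19-fold) were well above background with the mimic alone. Among members well above background on both arrays, 3 were at least 2-fold higher. MX1, an antiviral GTPase, was at 1.21 (63.1 and 131), the tethering protein BST2 at 1.09 and IFI27, chosen after its value was seen, at 1.02. The 16 measured genes of NF-kB and inflammatory signalling had a median of 0.31 (percentile 99.4), with TNF at 1.27 (11.2 and 24.4), TNFAIP2 at 0.53, IL6 at least 1.52-fold higher and IL1B at least 1.67-fold lower. The inflammatory list was not apart from matched lists among bright probes (median 0.04), without a background filter (0.02), with a floor (0.08) or by its mean (0.11).

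The small RNA machinery, which covers microRNA processing as well as silencing, was also higher as a list. Its 15 measured genes had a median of 0.21 (percentile 99.5), 11 lay above 0 and none reached 2-fold. TNRC6A, a scaffold of the silencing complex, was at 0.73, AGO4 at 0.64, TNRC6B at 0.31 and DROSHA, the nuclear microRNA processing enzyme, at -0.37. The list was no longer apart with the mean of each gene's probes (median 0.12) or by its mean (0.19).

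The NRF2 and metal response list went both ways. Of 24 measured genes, 5 were at least 2-fold higher, 4 were at least 2-fold lower and 15 lay within 2-fold, with a median of -0.10 (percentile 25.4). The higher ones were all metallothioneins, small metal-binding proteins: MT1F at 2.67 (110 and 628), MT1G at 2.46 (578 and 2870), MT1X at 2.40, MT1E at 2.29 and MT2A at 1.98 (15588 and 55197). Outside the list, MT1HL1 was at 2.32 and MT1M at 2.26. Of 17 metallothionein probes, 13 were well above background on both arrays, and each of these 13 was at least 2-fold higher, from 3.94-fold to 9.34-fold. Several of these probes are over 80% identical to another metallothionein probe, so the values of single metallothionein genes are uncertain. The lower ones included the NADPH-dependent reductases AKR1C1 at -1.52 (447 and 140) and AKR1B10, and the ferritin heavy chain gene FTH1 at -1.13. AKR1B10 was above background in the control alone and at least 1.22-fold lower. Among genes of the list well above background on both arrays, 3 were at least 2-fold lower. MT2A and FTH1 were chosen after their values were seen.

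**Figure D2:**
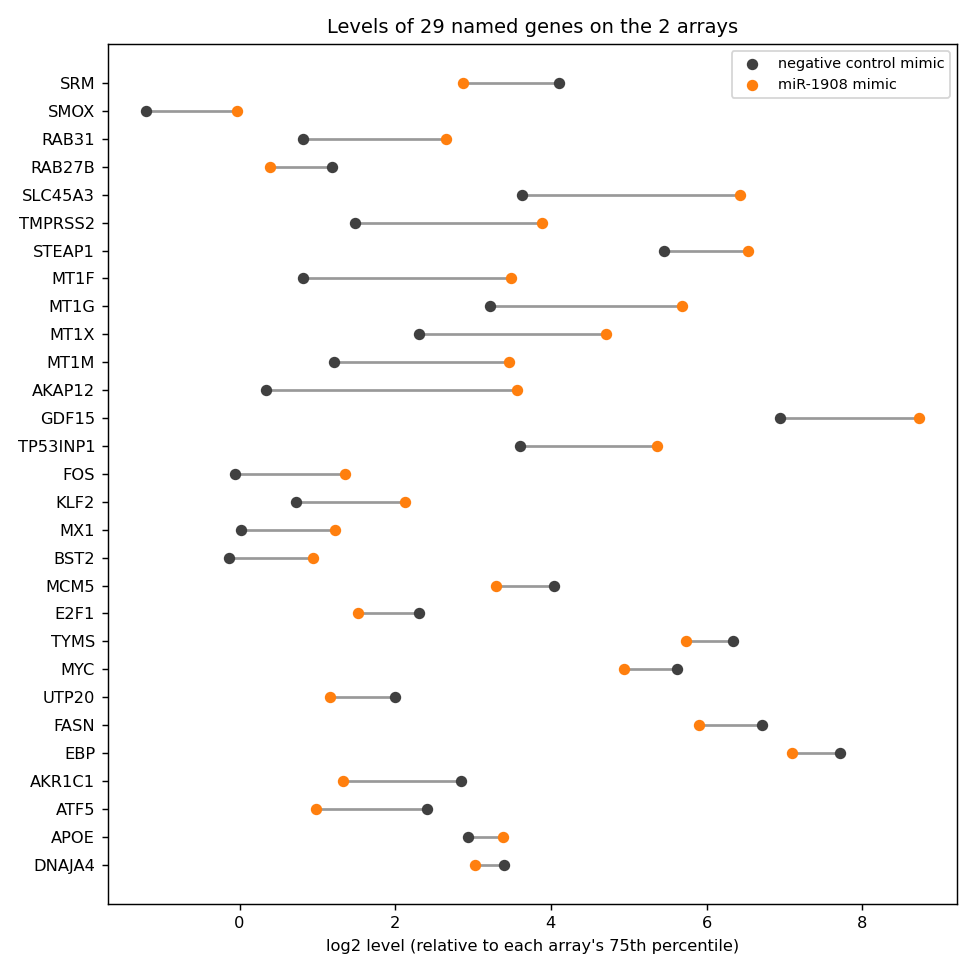
Log2 level relative to each array's 75th percentile (x axis) of 29 named genes on the negative control mimic array (dark points) and the miR-1908 mimic array (orange points), 1 row per gene. SRM, the S phase genes and MYC lie lower with the mimic, and SLC45A3, TMPRSS2, the metallothioneins and AKAP12 lie higher; levels of different genes are not comparable with each other.

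Metabolic genes were lower for cholesterol synthesis and close to matched lists elsewhere. Of 26 measured cholesterol synthesis genes, 21 lay below 0 and none reached 2-fold, with a median of -0.28 (percentile 0.05). The sterol isomerase EBP was at -0.62 (13047 and 7636), TMEM97 at -0.60 and the sterol carrier STARD4 at 0.66. Fatty acid synthesis genes had a median of -0.18 (percentile 5.79), with FASN, the fatty acid synthase, at -0.81 (6516 and 3336), AGPAT2 at 0.76, FADS3 at 0.70 and ELOVL1 at -0.59. Glycolysis and hypoxia genes had a median of -0.14 (percentile 15.3), with PGAM1 at -0.88, KDM3A at 0.79, PDK1 at -0.67 and the lactate exporter SLC16A3 at -0.66. Oxidative phosphorylation genes had a median of -0.10 (percentile 59.3), and 1 of 34, the ATP synthase subunit ATP5F1D, reached 2-fold at -1.003, with COX5A at -0.55, ATP5MC1 at -0.54 and CYCS at -0.37.

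Stress response lists were not apart from matched lists. The 24 unfolded protein response genes had a median of -0.003 (percentile 89.6), and the chaperones DNAJB9, PDIA4 and HSPA5 were at 0.48, 0.39 and 0.33. The 34 measured genes of ATF4 and amino acid stress had a median of -0.13 (percentile 12.03), with the glycine transporter SLC6A9 at -1.20, SESN2 at -0.79 and the glutamine transporter SLC1A5 at -0.60. The 27 p53 targets had a median of -0.09 (percentile 21.6). Even so, 2 of them were at least 2-fold higher, GDF15, a secreted stress cytokine, at 1.79 (7624 and 23695) and TP53INP1 at 1.76 (755 and 2309), while SESN2 and FAS were at -0.79 and -0.70.

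None of the lists of cell identity markers was apart from matched lists. The 24 measured epithelial and adhesion genes had a median of -0.01 (percentile 83.1), with ELF3 at 0.95, MARVELD2 at -0.64, DSP at 0.53 and OVOL1 at -0.45. Mesenchymal and matrix genes, which would mark fibroblasts, had a median of 0.22 over 16 measured genes (percentile 94.7), with DCN at 1.55 (11.03 and 29.1) and COL6A1 at 0.93. ACTA2 was at -0.72 and SNAI2 was at least 1.28-fold lower. Immune markers had a median of -0.01 over 11 measured genes (percentile 43.1), with GZMB at least 1.64-fold higher. Endothelial and basal epithelial markers had a median of 0.34 over 6 measured genes (percentile 93.8), with S100A2 at 0.81, LAMB3 at 0.73, VWF at 0.50 and CDH5 at 0.19.

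**Figure D3:**
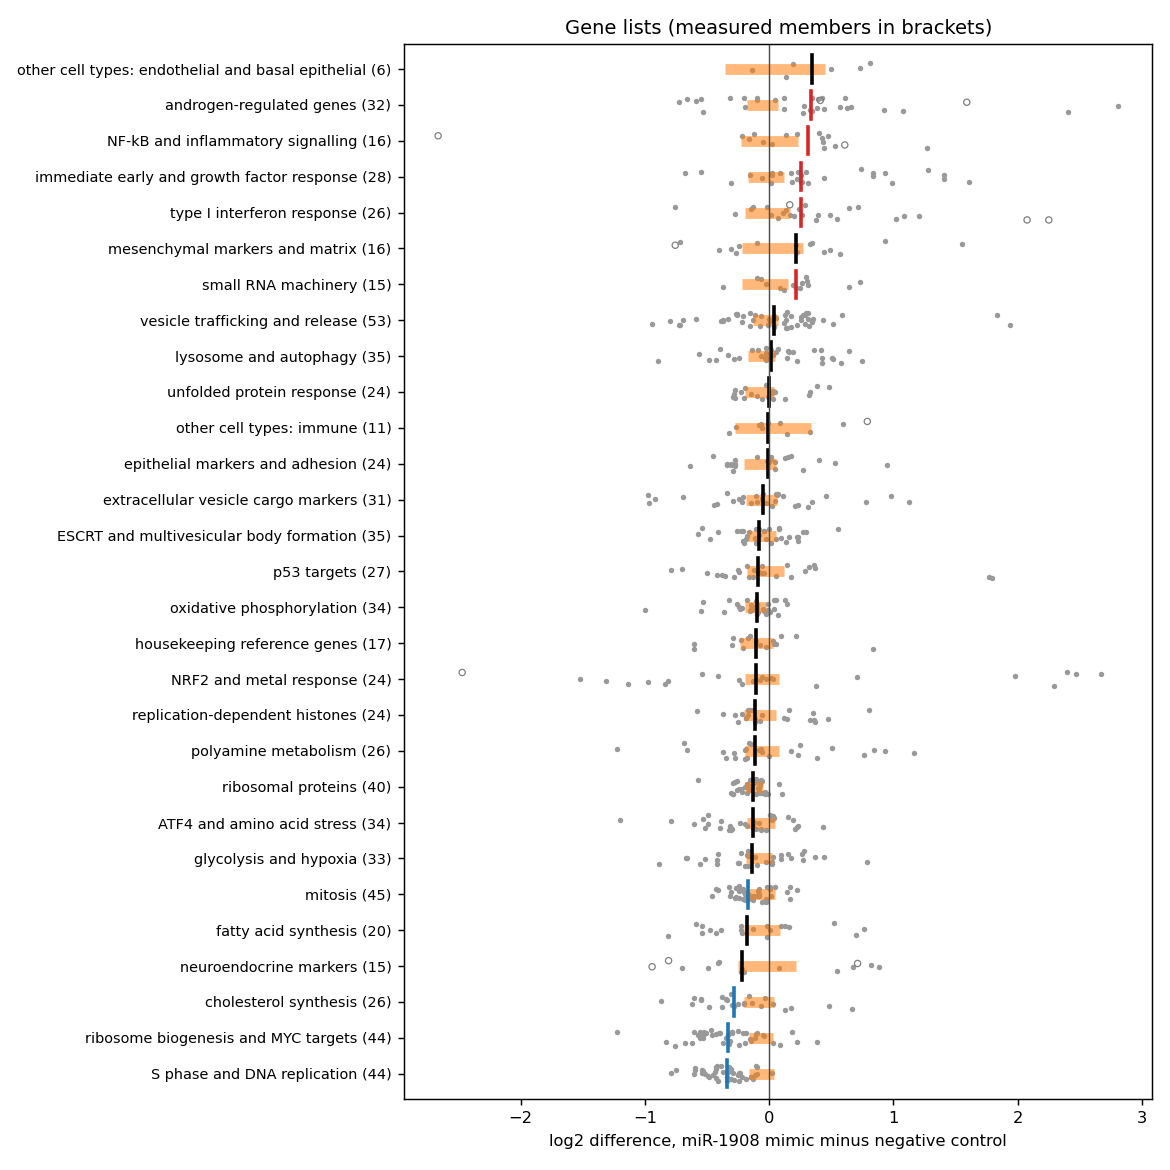
Log2 difference (miR-1908 mimic minus negative control mimic, x axis) of the measured members of 29 gene lists (rows), with filled points for genes well above background on both arrays and open points for those on 1 array. Vertical bars are list medians (red above and blue below the matched lists), orange bands hold the middle 95% of 10000 matched lists, and 5 lists lie above and 4 below their band.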

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

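Probes for ERCC control RNAs are outside the comparison of genes. Of 96 such probes, 2 were well above background in over 50% of their 9 spots on the miR-1908 mimic array and not on the control array, and 0 the other way round; 1 was so on both arrays. Their median processed signals were 9.05 with the mimic (7.55 in the control, where 4 spots were well above background) and 6.65 (5.79 in the control, with 3 such spots), close to the lowest signals called well above background (5.75 on the mimic array).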

How the results depend on the processing

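Scaling on the spike-ins and the GC correction were chosen after seeing the data; the other alternatives were planned. Among genes well above background on at least 1 array, the main counts of 1400 higher and 1014 lower became 99 and 96 after normexp correction, 136 and 74 for bright probes, 2851 and 1919 without a background filter, and 357 and 244 with a floor. They became 2839 and 2236 at 1.5-fold and 736 and 623 at 3-fold. Among genes well above background on both arrays, 498 higher and 259 lower became 80 and 59 after normexp correction, 136 and 74 for bright probes, and 312 and 169 with a floor. They became 1561 and 1276 at 1.5-fold, 137 and 39 at 3-fold, and 323 and 480 after spike-in scaling. All of these change the counts by construction: filters, floors and offsets through dim probes, thresholds through the cut itself, and the spike-in scaling by a shift of all genes. All 99 higher and 90 of the 96 lower genes after normexp correction were also in the main counts. Median scaling, quantile normalization, the authors' values, probe means and GC correction kept all 4 counts within 1.5 times.

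SRM lay between -1.40 and -1.18 under the alternatives run and stayed more than 2-fold lower. Of 9 lists called apart, 6 kept that call under each alternative: androgen-regulated genes, S phase, ribosome biogenesis and MYC targets, type I interferon, cholesterol synthesis and immediate early genes. The mitosis median lost its call after normexp correction (-0.18), quantile normalization (-0.10) and GC correction (-0.15) and as a mean (-0.14). The inflammatory list lost its call for bright probes (0.041), without a background filter (0.025), with a floor (0.079) and as a mean (0.11). The small RNA machinery lost its call with probe means (0.12) and as a mean (0.19). Vesicle trafficking was called apart after quantile normalization (0.12). The cause was not tested for these lists. FAAP20 was reversed, at 0.25, with the mean of its 7 probes, a mean that takes in 2 higher probes not well above background on either array. Of 143 named genes other than SRM, 18 dropped below 2-fold after normexp correction, 10 with the floor, 5 with probe means, 4 after spike-in scaling and 1 after quantile normalization. Spike-in scaling brought 7 others, and quantile normalization 4 others, to 2-fold. The planned seed match search in 3' UTRs or coding sequence, with its alternatives, was not run, as no transcript sequences were used. Signal over background limits dim genes most, since over 50% of gene probes were not well above background on either array taken alone.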

Other observations

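The gene groups in this paragraph and the next were chosen after their values were seen. Small Cajal body RNAs, which guide the modification of spliceosomal RNAs, were higher with the miR-1908 mimic. Of 20 measured, 17 lay above 0 and 3 were at least 2-fold higher (SCARNA20 at 1.498, SCARNA17 at 1.39 and SCARNA11 at 1.21), with a median of 0.59. Box H/ACA small nucleolar RNAs, 94 of them measured, had a median of -0.02 (percentile 39.15). The 117 box C/D small nucleolar RNAs had a median of -0.10, below most matched lists (percentile 0.39), and 42 of them lay above 0. Abundant small RNA genes often lie inside longer transcripts, and the probes were not checked for signal from these.

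Ferritin chains were unlike each other. FTH1, the heavy chain, was lower on each of 3 probes (-1.13, -1.11 and -0.99), while FTL, the light chain, was at 0.03, 0.07 and -0.01. The androgen-regulated kallikreins KLK2 and KLK3 showed modest differences on their brightest probes (0.40 and 0.39) and larger ones on dimmer probes (1.36 and 1.03). The co-chaperone FKBP5 was at 0.62. Of 4493 genes with at least 2 probes well above background on both arrays, 189 (4.21%) had probes that differed by at least 1 on the log2 scale.

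Explanations were then weighed for 3 patterns; the comparison of SRM with other ribosome biogenesis genes, the spike-in scaling and the GC and probe sequence tests were chosen after the arrays had been seen, and that of SRM with ribosome biogenesis genes after its result was known. An effect of the mimic itself stays open for each pattern, untested without further cultures.

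The first pattern is the 259 genes at least 2-fold lower among those well above background on both arrays. Probe GC content is argued against as the cause: across 25769 probes, Spearman's rho with the log2 difference was 0.046 (probes are not independent replicates), and 250 of the 259 genes stayed at least 2-fold lower after the GC trend was removed. Direct targeting through the 5p seed cannot be told apart from no targeting here, because a 60-base probe covers little of a transcript. The 63 probes with the seed match CCCCGCC had a median of 0.03, 25.2% of 127 other words of C and G gave a lower median, and 0 of the 259 genes had the match in their probe, against 57 of 20046 genes. When 6-base 5p matches were included (173 probes), the median was 0.09, above matched probes (percentile 99.99). The medians of the 127 other words of C and G centred on 0.097, so that value is close to those of such words. It is therefore no sign for or against targeting. For the 3p match (25 probes) the median was 0.26 (percentile 99.8), and the strand of the mimic is not stated.

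The second pattern is SRM. Scaling between arrays is argued against, since over normexp correction and median, quantile and spike-in scaling, the SRM difference closest to 0 was -1.18. The authors' values are nearly the main setting and the floor lies below both SRM signals, so neither adds a check. An array-wide trend with probe GC content is argued against as well, since that trend was nearly flat (Spearman's rho of 0.046 across probes). SRM was at -1.24 after its removal, but with so flat a trend this is no separate check. Among ribosome biogenesis genes and MYC targets, SRM was the lowest, and the lowest of the other members, UTP20, was at -0.83. That order was known before the comparison was set, and any list has a lowest member. It therefore cannot tell whether a general decrease of these genes accounts for the SRM difference. A direct effect of miR-1908 on SRM stays open too, and neither its transcript nor a second probe or culture was examined.

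The third pattern is the higher metallothionein probes. Of the higher probes, 4 (MT2A, MT1M, MT1G and MT1H) were at most 80% identical to any other metallothionein probe, so shared probe sequence is not common to all. Probes were compared only with each other, and transcripts of the paralogs were not searched. Cross-hybridisation therefore cannot be decided here, and single paralogs remain uncertain. A general metal response was predicted to raise the zinc exporter gene SLC30A1, which was at -0.060. It is a single gene with 1 array per group, so its value cannot decide for or against such a response. A bias with brightness is argued against, because the 200 nearest probes in brightness to each had medians of at most 0.17 in size.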
